A study of Oncorhynchus mykiss with 20 samples.

How the data were processed

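Messenger RNA was measured by RNA sequencing in whole intestines of rainbow trout (Oncorhynchus mykiss) fry from all-female cohorts. The samples came from 2 strains, here called Select and Commercial, at 20 and 65 days post hatch (dph), with 5 libraries in each of the 4 groups. Per the labels' protocols, RNA was purified with DNase treatment, poly(A) RNA was selected, stranded libraries were built and paired reads were sequenced on a NextSeq500. Per the labels' protocols the strains were kept in separate raceways after hatching, so raceway and strain cannot be separated in these samples.

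The deposited files hold 1 table per library with 78931 transcripts. Per the submitters' processing notes, Salmon 1.2.1 was used, a tool that assigns reads to transcripts by their sequence and divides reads that fit several transcripts between them. The release of the transcript set, the genome build and any read filter are not given in the sources used here. Per the file headers, each transcript has an expected count (an estimated number of read pairs, of which 34.3% were not whole numbers), a TPM (an abundance scaled for length and depth) and an effective length. Expected counts are not normalised; the deposited TPM values and effective lengths were used only in 1 alternative. Totals ran from 7314588 to 13682738 expected counts per library. Counting error is therefore small for abundant transcripts, while a gene without counts in a group of 5 libraries was given a floor of 3 counts over the group. Floors cover counting error only, because the reads carried no molecular identifiers.

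No genome came with the files. Transcripts were paired with genes through a RefSeq gene table of the assembly USDA_OmykA_1.1, which was used only for names and for which genes lie next to each other. The files' own build was not known, so no coordinates are given. Of the transcripts, 1083 matched that table with their version and 42376 without it, and the match without version was used. They fell into 25115 genes, 6926 with a symbol and 18189 with a LOC name. The 36555 unmatched transcripts were kept as single features, which gave 61670 features. Matched transcripts held 66.5% of all reads and genes with a symbol held 23.4%, so a gene list by symbol sees a minority of the reads. Trout carry many near-identical gene copies from an ancient genome duplication, and Salmon divides reads between such copies, so values of single copies are uncertain where copies are alike. An unmatched transcript of a gene is missing from that gene's sum.

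Expected counts were summed per gene and rounded to whole numbers. The tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, the filter filterByExpr by group, and a robust quasi-likelihood fit of 4 group means to all 20 libraries. The 2-sided quasi-likelihood F-test was followed by Benjamini-Hochberg adjustment over the 32166 features tested, and a feature is called at an adjusted p under 0.05. All adjusted p values of genes come from this test unless another tool is named. The contrasts were these: Select minus Commercial at each age, 65 minus 20 dph in each strain, and the difference between the age effects. Levels are given as CPM (counts scaled to a common library size, with TMM) with the SD over 5 libraries. Log2 fold changes are given with an approximate standard error (SE). It was derived as the size of the log2 fold change over the square root of the F statistic, and was not taken from the fit itself.

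Before the data were examined, 32 lists of genes by function or cell type were fixed, of which 6 had fewer than 5 tested genes and were not tested as lists. The lists were matched by gene symbol with paralog suffixes. The name patterns that belonged to the matching rule could not act, because no product names were available. The rule took in rrm2b with the cell cycle list and cpb2 with the liver list, and 1 gene, cpa5, belongs to both the exocrine pancreas and the macrophage list. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 26 lists tested within each contrast. Counts of members adjusted over the list alone pool both directions. Camera with an estimated correlation and fry were alternatives. Further liver and skeletal muscle markers outside the lists were written down after the data were seen, for 1 test of the closing section.

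The tests, filters, lists, alternatives and the rule for naming genes were also chosen before the data were examined. The rule takes, per pairwise contrast, the 10 genes with a symbol and the highest fold changes in each direction among called genes with a mean log2 CPM of at least 1 and groups that do not overlap. It also takes up to 4 called members per list, and for the difference between age effects up to 5 features in each direction. Not every gene that the rule takes is named in the text. Genes outside the rule are said to be chosen after their values were seen. The share of features with non-overlapping groups that chance gives is 0.794% for 5 libraries against 5.

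Alternatives were other size factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in at least 5 libraries, length-scaled TPM, transcripts as deposited, only the libraries of a contrast, a fit that is not robust, the replicate number as a block, exclusion of genes of neighbouring tissues, counts thinned to 7314544 per library, and each library left out in turn. Added after seeing the data were fits without the library labelled Commercial 65 dph replicate 2 and Select 65 dph replicate 5, which were nearly alike, and without these and Select 20 dph replicate 1. Without the alike libraries 32498 features were tested. TMM scaling left a median log2 difference of 0.04 over all features between ages in Commercial and 0.09 in Select; without any scaling it was 0.29 and 0.34, and with upper-quartile scaling it was 0.09 and 0.13. Values are reported relative to the TMM scaling.

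The pipeline was tested on simulated counts drawn with the real means and library sizes, with 100 features changed 2-fold and 100 changed 4-fold. Means were those over all libraries, changed features had a mean of at least 1 CPM, and features were drawn independently. The shares therefore do not cover changes in features of lower level, nor libraries that stand apart. Far fewer features were changed than were called with age in the real data (9680 in Commercial and 11019 in Select). The adjustment depends on that number, so the simulated shares for age do not describe the real age tests. For the strain contrast at 20 dph, on 30642 features, 32% of 2-fold and 71% of 4-fold changes were recovered, with 5 false calls. At 65 dph, on 30695 features, the shares were 43% and 76%, with 6 false calls. For age in Commercial, on 30626 features, they were 35% and 69%, with 7 false calls, and for age in Select, on 30671 features, 24% and 68%, with 2 false calls. For the difference between age effects, on 30702 features, they were 9% and 48%, with 0 false calls. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.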

Results

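Gene expression in the whole intestine was compared between a selected strain of rainbow trout (Select) and a common commercial strain (Commercial) at 2 early ages. The younger fry, at 20 dph, had been feeding for 10 days on a starter diet. The older fry, at 65 dph, were sampled shortly before a planned change of diet. Each of the 4 groups had 5 libraries. Totals averaged 10193880 expected counts (SD 1293476, n = 5) in Commercial and 8952676 (SD 760681, n = 5) in Select at 20 dph. They averaged 8425216 (SD 828198, n = 5) in Commercial and 9730185 (SD 2704591, n = 5) in Select at 65 dph. The first principal component of log2 CPM held 25.5% of the variance and separated the ages, and the second held 8.8%. On the second component 4 Commercial 65 dph libraries lay between -74.91 and -65.54 and 4 Select 65 dph libraries between 10.68 and 27.26. The library labelled Commercial 65 dph replicate 2 lay at 74.29, beside Select 65 dph replicate 5 at 76.72.

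**Figure D1:**
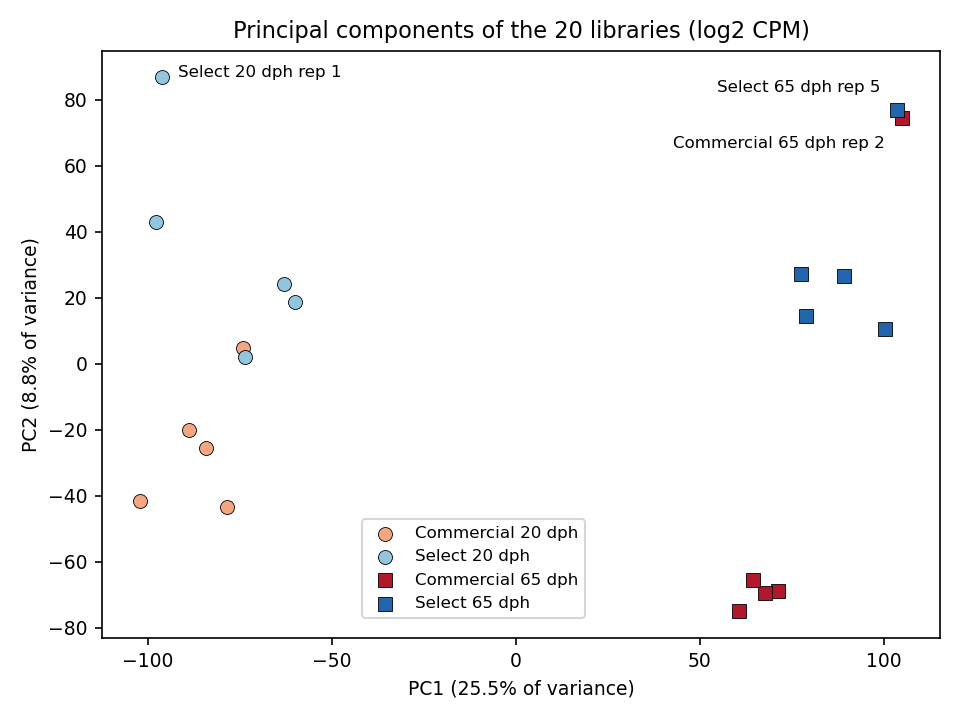
Principal components of log2 CPM, with the first component (25.5% of the variance) on the x axis and the second (8.8%) on the y axis, 1 point per library in 4 groups. The ages separate on the x axis, and the library labelled Commercial 65 dph replicate 2 lies at 74.29 on the y axis, away from the other Commercial libraries of its age.

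The first comparison asks how the strains differ soon after feeding starts. At 20 dph, Select intestines held more acsl4a, an enzyme that attaches coenzyme A to long-chain fatty acids, at 83.3 ± 24.5 CPM against 27.5 ± 5.24 in Commercial (SD, n = 5 each; log2 fold change 1.6 ± 0.24 SE, adjusted p = 0.0201). They also held more cd3e, a chain of the T cell receptor complex, at 7.28 ± 1.19 against 3.69 ± 0.63 CPM (0.98 ± 0.17, adjusted p = 0.0284). The same direction held for zgc:56585 at 58 ± 11.4 against 26.8 ± 4.63 CPM (1.11 ± 0.20, adjusted p = 0.0291). Also higher were tor2a, a torsin ATPase, at 32.7 ± 2.48 against 19.9 ± 2.92 CPM (0.72 ± 0.13, adjusted p = 0.0297) and slc66a3 at 13 ± 2.88 against 7.01 ± 1.08 CPM (0.89 ± 0.17, adjusted p = 0.0393). Lower in Select were dusp1, a phosphatase that switches off MAP kinases, at 7.46 ± 1.5 against 25.2 ± 13.9 CPM (-1.75 ± 0.33, adjusted p = 0.0387), and nr1d2a, a repressor of the circadian clock, at 17.6 ± 3.63 against 33.6 ± 8.65 CPM (-0.93 ± 0.18, adjusted p = 0.0454).

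As gene groups, the cholesterol synthesis list lay lower in Select at 20 dph, with a median log2 fold change of -0.44 (camera adjusted p = 0.00667; adjusted p = 0.870 with an estimated correlation). None of its 15 tested members was called over all features (0), and 2 were when adjusted over the list alone; tm7sf2, a sterol reductase, measured 309.8 ± 118 CPM in Select and 455 ± 92.9 in Commercial (SD, n = 5). The T cell and cytotoxic lymphocyte list lay higher, with a median of 0.35 (camera adjusted p = 0.0122; adjusted p = 0.870 with an estimated correlation). Of its 11 tested members cd3e was called (1 over all features and 1 adjusted over the list alone), and members that were not called went both ways, such as il7r at 0.31 and prf1 at -0.46. The cholesterol call was lost without Select 20 dph replicate 3 (adjusted p = 0.0527) or replicate 4 (0.0812), and the T cell call without Commercial 20 dph replicate 4 (0.0645) or Select 20 dph replicate 4 (0.0812). The liver list was not called (median 2.61, adjusted p = 0.332), but most of its members, though not cps1 and tf, stood far above the other 20 dph libraries in Select 20 dph replicate 1. Without that library its median was -0.92 and it was called (adjusted p = 0.0252; adjusted p = 0.645 with an estimated correlation). Liver list genes also held 0.0344% of reads in Commercial 20 dph replicate 5, against 0.0039% to 0.0122% in the other Commercial 20 dph libraries. Without Select 20 dph replicate 1 lists of nutrient transporters (median 0.36, adjusted p = 0.014), endocytosis and lysosome (0.32, adjusted p = 0.00106) and MHC class I presentation (0.12, adjusted p = 0.02) were called as higher in Select as well. For these 3 lists the adjusted p was 0.559, 0.645 and 0.656 with an estimated correlation. The endocytosis and lysosome list was also called without Commercial 20 dph replicate 3 (adjusted p = 0.0282) or 5 (0.0372), and fatty acid oxidation, which was not called with all libraries (adjusted p = 0.0786), without Commercial 20 dph replicate 2 (0.0242) or Select 20 dph replicate 2 (0.00933). With an estimated correlation these adjusted p were 0.864, 0.956, 0.896 and 0.751.

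In all, edgeR called 51 of 32166 features between strains at 20 dph, 34 higher and 17 lower in Select, of which 7 had a symbol, 19 a LOC name and 25 were single transcripts. Groups did not overlap for 706 of all tested features (2.19%), where chance gives 0.794%, and for 48 of those called. Counts without 1 library ran from 5 to 46: 5 without Commercial replicate 2, 7 without Commercial replicate 4, 13 without Commercial replicate 1 and 27 without Commercial replicate 3, 10, 16, 26 and 28 without Select replicates 4, 2, 3 and 5. Of the genes named, acsl4a lost its call only without Commercial replicate 2, cd3e with any of 7 of the 10 libraries left out, zgc:56585 and dusp1 with 8, and tor2a, nr1d2a and slc66a3 with 9. Across those fits the fold change of cd3e stayed between 0.89 and 1.06 and that of dusp1 between -1.90 and -1.36.

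The comparison was repeated at 65 dph. With the libraries as labelled, 0 features were called by edgeR, 2000 had an unadjusted p under 0.05 (6.22% of those tested), and DESeq2 called 178 and limma-voom 0. The cholesterol synthesis list again lay lower in Select, with a median log2 fold change of -0.48 (camera adjusted p = 0.017; adjusted p = 0.905 with an estimated correlation). Of its 15 tested members 0 were called and 0 when adjusted over the list alone. That call was lost without Commercial replicate 4 (adjusted p = 0.105), Commercial replicate 5 (0.194), Select replicate 3 (0.0614) or Select replicate 5 (0.457).

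The count at 65 dph rests on the library labelled Commercial 65 dph replicate 2: without it 125 features were called, without Select replicate 5 there were 7, and without Commercial replicate 4, Select replicate 1 or Select replicate 2 there was 1. With both alike libraries left out (4 against 4, a choice made after seeing the data), 53 features were called, 21 higher and 32 lower in Select, 10 of them with a symbol. Groups did not overlap for 2778 of all tested features (8.55%), where chance gives 2.86%, and for the 53 called. Higher in Select in that fit were grpel2, a cofactor of the mitochondrial chaperone HSP70, with a log2 fold change of 1.49 ± 0.22 (SE, adjusted p = 0.0131), and zgc:56585 with 1.02 ± 0.16 (adjusted p = 0.0185). Lower were mt2, a metallothionein that binds zinc and copper, at 593 ± 134 CPM against 1409 ± 318 in Commercial (SD, n = 4; -1.25 ± 0.24, adjusted p = 0.0482), zgc:158868 (-1.25 ± 0.15, adjusted p = 0.0057), the phospholipase pla2g4ab (-1.43) and the transcription factor glis3 (-1.48). Further genes with lower values in Select were pnp4b, a purine nucleoside phosphorylase (-0.98), gnpnat1, an enzyme of amino sugar synthesis (-0.65), and rpap1 (-0.60). In this fit the fibroblast and extracellular matrix list was called as higher in Select, with a median of 0.62 and 5 of 7 members called when adjusted over the list alone, but 0 over all features (camera adjusted p = 0.00548; adjusted p = 0.915 with an estimated correlation). With all libraries its adjusted p was 0.0604, and without only Commercial replicate 2, Select replicate 3 or Select replicate 4 it was 0.000788, 0.000514 and 0.0116 (0.740, 0.996 and 0.956 with an estimated correlation). The cholesterol list was called too (median -0.55, camera adjusted p = 0.00548; adjusted p = 0.915 with an estimated correlation).

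To ask whether the same genes differed at both ages, calls were intersected. With all libraries the overlap was 0 because no feature was called at 65 dph by edgeR; with DESeq2 it was 34. Without the alike libraries 8 features were called at both ages in the same direction, 6 higher and 2 lower in Select, where independent lists would share 0.0498 (one-sided Fisher's exact test over features, which are not independent, p = 1.54e-13). The 8 features were zgc:56585, cntn3a.1, 3 LOC genes and 3 single transcripts. The alike libraries were left out because of where they lay, which favours calls at 65 dph. Both contrasts also share the same estimate of spread for a feature, so 0.0498 may be too low for comparison. The gene cntn3a.1, a cell adhesion protein named after its values were seen, had 0 counts in the 4 Commercial 65 dph libraries. It was at least 32.6-fold higher in Select, or at least 23.4-fold without Commercial 65 dph replicate 1. At 20 dph its log2 fold change was 3.89 ± 0.70 (adjusted p = 0.0454).

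**Figure D2:**
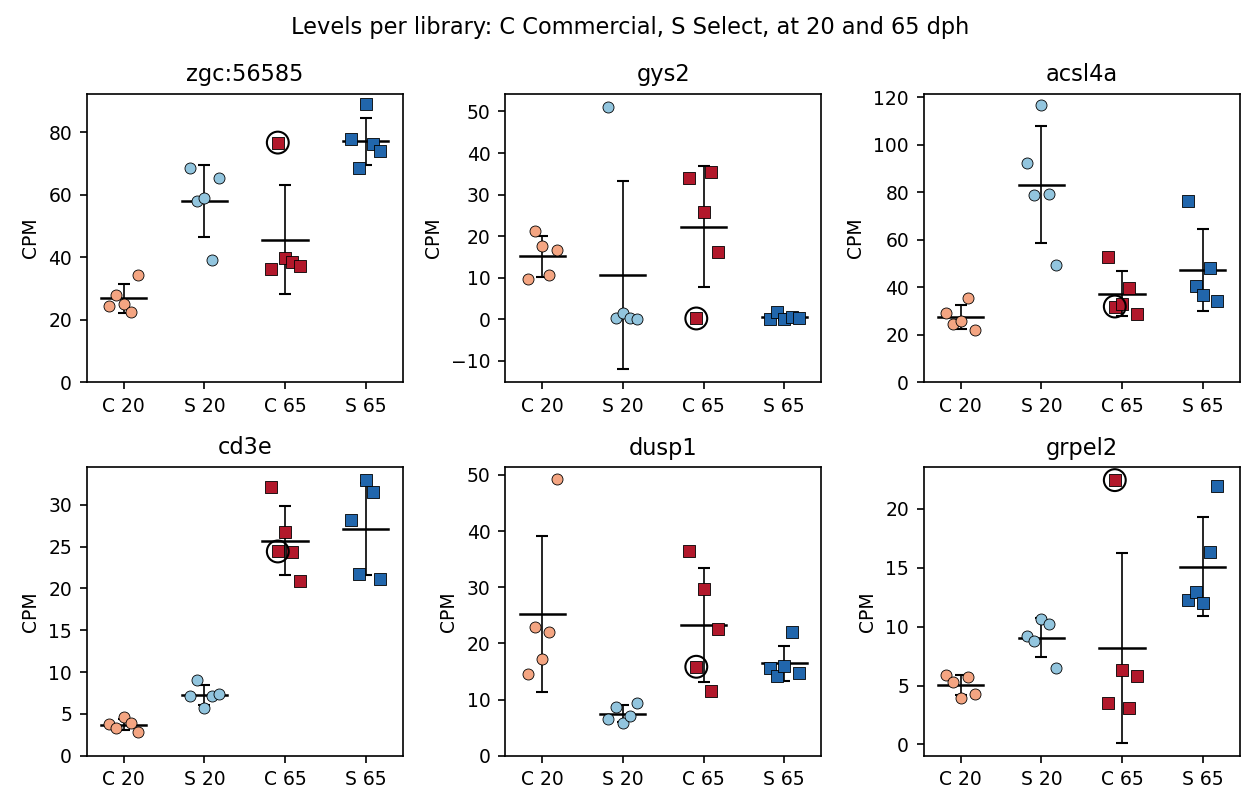
Levels in CPM on the y axis for genes called between strains, with all libraries or without the alike ones, and for gys2, chosen after its values were seen. Each point is 1 library, and bars lie at the mean ± SD of 5 libraries in each of the 4 groups. The circle marks the library labelled Commercial 65 dph replicate 2, at 76.6 CPM for zgc:56585, where the other 4 Commercial 65 dph libraries lie between 36.3 and 39.6.

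The next comparison asks how the intestine changes from 20 to 65 dph within the Commercial strain. Genes of cholesterol synthesis fell: 14 of 15 tested members were called lower and 0 higher, with a median log2 fold change of -2.93 (14 adjusted over the list alone). The sterol reductase tm7sf2 fell from 455 ± 92.9 to 36.2 ± 17.9 CPM (SD, n = 5; -3.65 ± 0.37 SE, adjusted p = 1.43e-06), and nsdhl, another enzyme of the pathway, fell by 2.93 on the log2 scale. T cell and cytotoxic genes rose in 9 of 11 tested members with 0 lower, with a median of 1.96 (9 adjusted over the list alone). The coreceptor cd8a rose from 0.105 ± 0.0649 to 5.89 ± 1.79 CPM (5.61 ± 0.59, adjusted p = 1.93e-06), and cd3e rose by 2.79. The interleukin 7 receptor il7r rose by 2.18 and prf1, which encodes perforin, by 1.96. Cell cycle genes fell in 11 of 14 members, with a median of -1.89 (11 adjusted over the list alone), among them top2a, a topoisomerase of dividing cells, from 152 ± 20.6 to 36.5 ± 10 CPM (-2.05 ± 0.18, adjusted p = 4.31e-07) and kif20a (-2.32).

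Other lists followed in Commercial. Fatty acid oxidation genes fell in 13 of 17 members, with a median of -1.18 (14 called in either direction when adjusted over the list alone), such as decr1, an auxiliary enzyme for unsaturated fatty acids (-1.40), etfa (-1.39) and the carnitine carrier slc25a20 (-1.34). The 1 member that rose was pparab, a nuclear receptor and not an enzyme of the pathway, named after its value was seen (0.91). Interferon-stimulated genes rose in 10 of 22 members with 0 lower (10 adjusted over the list alone; median 0.72), with helz2a at 4.36, ifit8 at 3.27 and trim25 at 0.88. Genes of endocytosis and the lysosome rose in 7 of 12 members (9 adjusted over the list alone; median 0.76), among them the cystine exporter ctns (2.21) and the cathepsins ctsh (1.6) and ctsa (1.06). Lipid absorption and lipoprotein genes fell in 3 of 5 members (3 adjusted over the list alone; median -1.08): apoba, the structural protein of lipoproteins, fell from 98.7 ± 27.6 to 0.559 ± 0.484 CPM (-7.38 ± 0.90, adjusted p = 1.04e-05), and fabp2, the intestinal fatty acid binding protein, by 0.88. Ribosomal protein genes fell in 4 of 7 members (4 adjusted over the list alone; median -0.31), such as rpl10 (-0.65) and rpl7a (-0.50).

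Genes with the widest changes in Commercial included chia.1, an acidic chitinase, which fell from 1071 ± 783 to 0.469 ± 0.316 CPM (SD, n = 5; -11.09 ± 1.44, adjusted p = 1.83e-05), and mep1b, a brush-border metalloprotease. The latter had 0 counts in all 5 libraries at 65 dph and was at least 2440-fold lower than at 20 dph, or at least 1600-fold without Commercial 20 dph replicate 1 (edgeR adjusted p = 0.00161; limma-voom 0.391). The water and glycerol channel aqp10a fell by 7.57 (by 8.29 without the library labelled Commercial 65 dph replicate 2). Upward, the chemokine cxcl8c rose by 4.52 and hba1, a hemoglobin chain, by 4.32.

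The test called 9680 features in Commercial, 4657 higher and 5023 lower at 65 dph, 4633 of them with a log2 change over 1 in size. Camera called the 8 lists described. The adjusted p was 5.03e-15 for cholesterol synthesis (0.04996 with an estimated correlation, just under the threshold), 3.45e-10 for fatty acid oxidation (0.04996 with an estimated correlation) and 8.45e-09 for the T cell list (0.0182 with an estimated correlation). For the cell cycle list it was 8.45e-09 (adjusted p = 0.107 with an estimated correlation), for the endocytosis and lysosome list 0.000442 (adjusted p = 0.446 with an estimated correlation) and for interferon-stimulated genes 0.000458 (adjusted p = 0.272 with an estimated correlation). For ribosomal proteins it was 0.0235 (adjusted p = 0.676 with an estimated correlation), and for lipid absorption 0.0251 (adjusted p = 0.201 with an estimated correlation, and 0.0634 without Commercial 20 dph replicate 5). The library labelled Commercial 65 dph replicate 2 is among these 5, and without it and its alike library 9039 features were called.

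**Figure D3:**
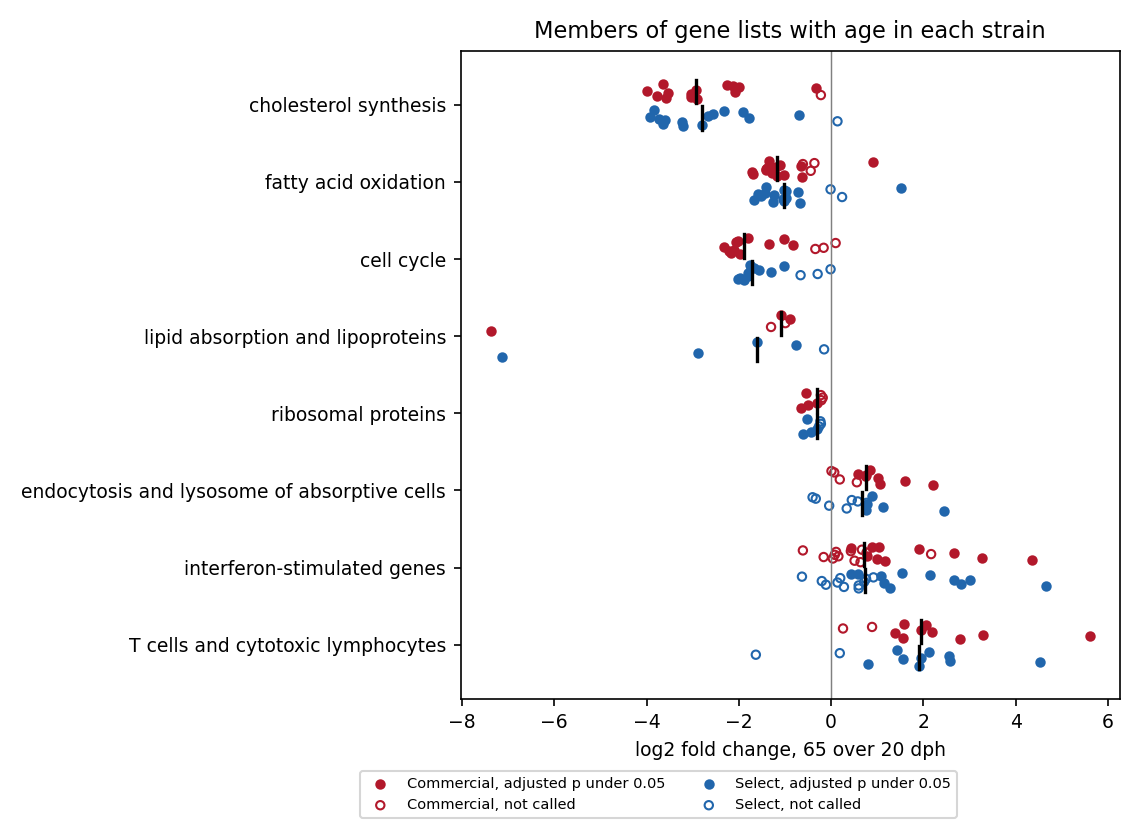
Log2 fold change from 20 to 65 dph (x axis) of the tested members of 8 gene lists (y axis) in Commercial (red) and Select (blue), with 1 point per gene, filled where the adjusted p was under 0.05, and a black bar at the median of the list. Medians of the cholesterol synthesis list lie at -2.93 and -2.80, and those of the T cell list at 1.96 and 1.90.

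The same comparison in the Select strain gave the following. Cholesterol synthesis genes fell in 14 of 15 members with a median of -2.80 (14 adjusted over the list alone), with tm7sf2 falling from 309.8 ± 118 to 21.7 ± 7.27 CPM (SD, n = 5; -3.83 ± 0.37 SE, adjusted p = 1.5e-06). The gene fdft1, the first enzyme committed to sterols, fell by 3.65. T cell genes rose in 9 of 11 members (9 adjusted over the list alone; median 1.90), with cd8a rising from 0.273 ± 0.269 to 6.64 ± 1.35 CPM (4.54 ± 0.54, adjusted p = 7.38e-06), prf1 by 2.55, il7r by 1.95 and cd3e by 1.90. Cell cycle genes fell in 11 of 14 members (12 adjusted over the list alone; median -1.70), with top2a at -1.67 and kif20a at -1.79. Fatty acid oxidation genes fell in 14 of 17 (15 called in either direction when adjusted over the list alone; median -1.03), with etfa at -1.59 and decr1 at -1.24, and pparab rose (1.51). Interferon-stimulated genes rose in 11 of 22 (13 adjusted over the list alone; median 0.74), with helz2a at 4.67 and ifit8 at 2.82. Endocytosis and lysosome genes rose in 5 of 12 (8 adjusted over the list alone; median 0.66), with ctns at 2.46. Lipid absorption genes fell in 4 of 5 (4 adjusted over the list alone; median -1.61), with apoba at -7.13, or -5.87 without Select 20 dph replicate 1, and fabp2 at -0.76. Ribosomal protein genes fell in 4 of 7 (4 adjusted over the list alone; median -0.30).

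Called by camera in Select and not in Commercial were the lists of endothelium and erythrocytes, of B cells and of liver, and with all libraries the difference between strains was not called by camera for any of them (adjusted p = 0.0557, 0.851 and 0.377). For endothelium and erythrocytes it was called with the stricter filter (adjusted p = 0.0422; adjusted p = 0.937 with an estimated correlation) and without 3 libraries (0.026; adjusted p = 0.549 with an estimated correlation). It was also called without Commercial 20 dph replicate 2 (0.0463) or 3 (0.0299), or Select 20 dph replicate 1 (0.0245) or 2 (0.031). The same held without the library labelled Commercial 65 dph replicate 2 (0.0136), or Select 65 dph replicate 3 (0.00948) or 4 (0.0294). With an estimated correlation the lowest of these 7 was 0.676. With an estimated correlation the adjusted p in Select was 0.571, 0.144 and 0.571. In Commercial the B cell list had a camera adjusted p of 0.0757, and 0.0493 without Commercial 65 dph replicate 1 (0.199 with an estimated correlation), and fry called it in both strains (adjusted p = 0.000104 and 2e-05). Endothelium and erythrocyte genes rose in 4 of 9 members (4 adjusted over the list alone; median 0.85), with hba1 rising from 2.83 ± 2.50 to 76.6 ± 13.8 CPM (SD, n = 5; 4.74 ± 0.55, adjusted p = 6.93e-06; 5.36 without Select 20 dph replicate 4), hbb1 by 2.85 and plvapa, a protein of endothelial pores, by 1.2. B cell genes rose in 4 of 7 (4 adjusted over the list alone; median 0.66), with cd79b, a chain of the B cell receptor, at 1.83 and cd40 at 0.76. Liver genes fell in 9 of 10 (9 adjusted over the list alone; median -5.76), among them c5 (-7.56), f2 (-6.61) and ambp (-4.91). Those liver values rest on Select 20 dph replicate 1: without it the list was not called (median -0.66, adjusted p = 0.232), and the 3 genes stood at -1.20, -3.75 and -2.07. The acidic chitinase chia.1 fell by 7.49 (by 10.37 without Select 65 dph replicate 3), mep1b was at least 1340-fold lower with 0 counts at 65 dph, or at least 889-fold without Select 20 dph replicate 2 (edgeR adjusted p = 0.0022; limma-voom 0.393), and aqp8a.2, a water channel, rose by 6.43 (by 7.08 without Select 20 dph replicate 5).

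The test called 11019 features in Select, 5264 higher and 5755 lower, 5349 of them with a log2 change over 1 in size. Camera called 11 lists, and 0 kept the call with an estimated correlation. Smooth muscle was called as well without Select 65 dph replicate 3 (adjusted p = 0.0124) or 4 (0.0355). With an estimated correlation these were 0.468 and 0.543. Enteric neurons and glia (0.0393) and fibroblast and extracellular matrix (0.0299) were called without Select 65 dph replicate 3 (0.468 and 0.486 with an estimated correlation). The adjusted p was 1.35e-13 for cholesterol synthesis (adjusted p = 0.0788 with an estimated correlation), 1.30e-08 for the cell cycle (adjusted p = 0.107 with an estimated correlation), 1.34e-08 for fatty acid oxidation (adjusted p = 0.0932 with an estimated correlation) and 5.71e-06 for T cells (adjusted p = 0.0788 with an estimated correlation). It was 0.00199 for interferon-stimulated genes (adjusted p = 0.364 with an estimated correlation), 0.0167 for lipid absorption (adjusted p = 0.137 with an estimated correlation), and 0.0209 for endocytosis and lysosome (adjusted p = 0.571 with an estimated correlation; 0.0547 without Select 20 dph replicate 1). For ribosomal proteins it was 0.0264 (adjusted p = 0.571 with an estimated correlation; 0.0539 without Select 20 dph replicate 2 and 0.0604 without Select 65 dph replicate 2), and for endothelium and erythrocytes 0.0264 (adjusted p = 0.571 with an estimated correlation; 0.0525 without Select 20 dph replicate 5). For B cells it was 0.028 (adjusted p = 0.144 with an estimated correlation; 0.0523 without Select 20 dph replicate 1), and for liver 0.0292 (adjusted p = 0.571 with an estimated correlation). Between the strains, 7398 features were called in both in the same direction, 3278 higher and 4120 lower at 65 dph, and 6 in opposite directions. Independent lists of these sizes would share 1660 in the same direction.

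The last comparison asks whether the strain difference changes with age. No feature was called by edgeR (0), 1781 had an unadjusted p under 0.05 (5.54% of those tested), and DESeq2 called 97 and limma-voom 0. Without single libraries 1 feature was called when Commercial 20 dph replicate 4, Commercial 65 dph replicate 4, Select 65 dph replicate 1 or Select 65 dph replicate 2 was left out, and 2 without Select 65 dph replicate 5. No list was called (0 of 26). Lists were called without Commercial 20 dph replicate 2 (2), 3 (4) or 4 (3), Select 20 dph replicate 1 (3) or 2 (3), the library labelled Commercial 65 dph replicate 2 (6), and Select 65 dph replicate 3 (6) or 4 (2). The fibroblast and extracellular matrix list was among those called in each of these fits, with adjusted p from 0.000604 to 0.0467 (from 0.555 to 0.995 with an estimated correlation). Endothelium and erythrocytes were called in 7 of these 8 fits and enteric neurons and glia in 5. Smooth muscle was called in 3, endocytosis and lysosome in 2 and MHC class I in 1. With an estimated correlation 0 of these calls held, with a lowest adjusted p of 0.676, 0.555, 0.718, 0.676 and 0.816 for the 5 lists in this order. T cells were called in 3, with negative medians such as -0.57 without Select 65 dph replicate 3 (adjusted p = 0.0155; adjusted p = 0.555 with an estimated correlation). The lowest adjusted p was 0.0557, shared by the lists of fibroblast and extracellular matrix, enteric neurons and glia, and endothelium and erythrocytes. Without the alike libraries 2 features were called. LOC110493747 had a log2 difference between age effects of -5.64 ± 0.63 (SE, adjusted p = 0.00359): it measured 42.9 CPM in Select 65 dph replicate 5, between 0.596 and 0.854 CPM in the other 4 Select 65 dph libraries, and 48.6 ± 24.3 CPM in Commercial 65 dph (SD, n = 5). A single unmatched transcript, XM_021596205.1, had a difference of 2.27 ± 0.32 (adjusted p = 0.0361). In that fit the fibroblast and extracellular matrix list was called (median 0.79, camera adjusted p = 0.00288; adjusted p = 0.898 with an estimated correlation), with 0 of 7 members called over all features and 4 when adjusted over the list alone.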

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

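The tests of a wrong label, of a swap, of liver and skeletal muscle RNA and of strain differences shared by both ages were chosen only after the result was seen. Single libraries far from the other 4 of their group were searched for in 196 groups of values, and 24 were found where chance gives 9.8, since chance flags about 1 in 20 groups. The search took in genes named in the text, among them gys2, chosen after its values were seen. It also took in the skeletal muscle list, too small to be tested as a list. Many groups share libraries, so 9.8 is only a rough guide. The value given for each library that stood apart is the gap to the nearest other library over the range of the group.

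The library labelled Commercial 65 dph replicate 2 stood apart from its group on the first and second principal components (gap 0.76 and 0.937), in reads of untested features (0.971), in the lists of endocytosis and lysosome (0.747), smooth muscle (0.856) and fibroblast and extracellular matrix (0.775), and in zgc:56585 (0.882) and gys2 (0.825). Select 65 dph replicate 5 stood apart from its own group on the second component (0.749), in reads of untested features (0.722), in endocytosis and lysosome (0.729) and in tor2a (0.786).

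These 2 libraries were the most alike of 45 pairs at 65 dph, with a median chi-square over features of 0.785 against 1.627 for the next pair and 0.455 from sampling alone. A makeup of tissues shared by 2 different fish was argued against by the 6267 features that vary least. There the pair's median was 0.704 against 1.053 for the next closest pair, a ratio of 0.669. The pair stood less far from the next pair there than over all features, so a shared makeup is not excluded. A swap was argued against because 0 Select 65 dph libraries lay in the Commercial range of a strain axis built from 45 genes at 20 dph. A single wrong strain label, or material of a Select fish in this library, may be the source: it lay at 1.22 on that axis, just above the Select range, where other Commercial libraries lay between -0.269 and 0.294 and Select libraries between 0.905 and 1.129. Whether the 2 libraries came from 1 fish stays open.

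Select 20 dph replicate 1 stood apart with higher values in the liver list (0.891) and the skeletal muscle list (0.725). It was higher in tfa, a transferrin made by the liver (0.727), and in reads of untested features (0.993), and lower in nutrient transporters (0.817). Liver list genes held 1.7673% of its reads against 0.0035% to 0.011% in the other Select 20 dph libraries, with tfa at 9604 CPM and 12 of the 14 tested members of both lists at their highest value of 20 dph, and no sort or gate was applied that would remove other tissues. A lower share of gut epithelium was argued against as the source of the high liver and skeletal muscle values. The smooth muscle, neuron and fibroblast lists rose at most 0.0407 times as much on the log2 scale as the skeletal muscle list. Whether the epithelial share was lower is not decided by this. Against the other Select 20 dph libraries, nutrient transporters stood at -0.9, endocytosis and lysosome at -0.72 and brush-border enzymes at -0.43. Lipid absorption stood at 1.75. RNA of liver and skeletal muscle in the library stays open: of 24 further tested markers outside every list, 54.2% had their highest value at 20 dph there (9 of 16 for liver, 4 of 8 for skeletal muscle), between the 80% set as needed and the 50% set as excluding it. That share counts only which library was highest, not by how much. It also counts only markers that passed the filter, which drops a gene present in no other library. Features that were not tested held 6.41% of the reads of this library, against 0.36% to 0.4% in the other Select 20 dph libraries. The share therefore cannot decide on this library. Among liver markers highest there, cfh measured 1500 CPM against at most 13.5 in any other library of 20 dph. Among the rest, c6 measured 40 CPM there and up to 115 elsewhere at 20 dph. A biological difference of this fish stays untested.

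Strain differences without the alike libraries are the last pattern weighed. Of the genes called at 20 dph from those libraries alone, 97.8% had the same sign at 65 dph (95.6% with all libraries), so a difference between strains at both ages may underlie them. Without the alike libraries the log2 fold changes of these genes at the 2 ages correlated at 0.71. The median ratio of the value at 65 dph to that at 20 dph was 0.46. Calls at 20 dph favour large values there, so this ratio does not measure a change with age. Of 56 placed called genes, 17.9% had another called gene among the 5 nearest tested genes on each side, where the 95th percentile of 1000 random sets was 10.7%, so genome blocks that differ between the strains may contribute. Tandem or overlapping genes that share reads could give the same value, and this was not tested. Variants of a strain against the reference and the separate raceways also stay open.

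The other libraries that stood apart were these, given as values. Commercial 20 dph replicate 1 had a higher total (0.769) and a lower xenobiotic metabolism list (0.716). Commercial 20 dph replicate 5 had more reads in untested features (0.909) and a lower unfolded protein response and heat shock list (0.727). At 65 dph, dusp1 was higher in Select replicate 4 (0.724) and chia.1 in Select replicate 3 (0.726), and tfa was lower in Commercial replicate 1 (0.713).

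The libraries of each contrast were also divided in other ways. For genes between strains at 20 dph chance is unlikely but not excluded, with the real split the 1 of 60 drawn to reach 51 calls (highest other 38). Chance cannot be excluded for lists (2 called, highest other 8, 38 splits with as many). At 65 dph it cannot be excluded for lists (1 called, highest other 9, 53 splits). For genes 0 were called (highest other 344), a count that each of the 60 splits reaches, so the splits decide nothing. Splits that put the library labelled Commercial 65 dph replicate 2 with 4 Select libraries called 201, 344 and 167 features, which points to a structure of the samples. Without the alike libraries 53 genes were called at 65 dph (highest other 2, the real split the 1 of 35 to reach it), but these libraries were left out because of where they lay, which favours the real split, so chance is not excluded by this. For age chance is very unlikely for genes in Commercial (9680, highest other 715, 1 split) and Select (11019, highest other 84, 1 split). The count of lists does not exclude it (8 called, highest other 11, 7 splits, and 11 called, highest other 13, 8 splits). Some of these splits kept 4 libraries of an age together, so the count of lists cannot decide. It also tests no single list. For the difference between age effects the splits decide nothing either, since 0 genes (highest other 7) and 0 lists (highest other 9) were called and each of the 60 splits reaches that.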

How the results depend on the processing

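The fits without the 2 alike libraries, and without these and Select 20 dph replicate 1, were tests chosen only after the result was seen. Age effects moved least: with other settings and single libraries left out, 7831 to 10881 features were called in Commercial and 9193 to 12126 in Select, all within 1.5 times the counts of 9680 and 11019, and the overlap ran from 5191 to 8065. Between strains at 20 dph (51 called), DESeq2 called 513, limma-voom 29, no filter gave 31, transcripts as deposited 2 and the replicate block 20, and without single libraries 5 to 46 were called. At 65 dph (0 called), DESeq2 called 178, the libraries of the contrast alone gave 1, the fit without the alike libraries 53 and without 3 libraries 71, and without single libraries 0 to 125. For the difference between age effects (0 called), these were 97 with DESeq2, 2 without the alike libraries, 1 without 3 libraries and 0 to 2 without single libraries. The overlap of strain calls (0) was 34 with DESeq2, 8 without the alike libraries, 8 without 3 libraries and 0 to 10 without a replicate number. The cause was not tested.

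Called lists between strains at 20 dph (2) were 0 with an estimated correlation, 0 with fry, 5 without 3 libraries and 0 to 6 without single libraries; at 65 dph (1) they were 0, 0, 2 without the alike libraries, 2 without 3 libraries and 0 to 2. With an estimated correlation 3 lists were called for age in Commercial (2 of them at an adjusted p of 0.04996) and 0 in Select, with fry 11 and 15, and without single libraries 7 to 9 and 8 to 14. For the difference between age effects (0) they were 4 with the stricter filter, 1 without the alike libraries, 3 without 3 libraries and 0 to 6 without single libraries. Those 4 were enteric neurons and glia, fibroblast and extracellular matrix, endothelium and erythrocytes, and T cells. Each had a camera adjusted p of 0.0422, and 0.937 with an estimated correlation. The cause was not tested. Without Select 20 dph replicate 1 the direction reversed for the liver list between strains at 20 dph (-0.92; single-library range -0.92 to 2.98) and for c9 (0.82; range -8.31 to 0.82), myl1 (2.21; range -6.26 to 2.21) and pvalb1 (1.04; range -7.91 to 1.04) with age in Select. Without 3 libraries myl1 stood at 2.45 and pvalb1 at 1.35. In that library 12 of the 14 liver and skeletal muscle list members had their highest value of 20 dph. Of the fits of named genes, 1923 of 1992 kept direction and side of the threshold for age in Commercial, 2278 of 2436 for age in Select, and 87 of 161 for strain at 20 dph. For strain at 65 dph 9 genes, none called with all libraries, were followed. Of their 207 fits 176 stayed without a call and 31 gained one. The 9 genes were taken from the calls made without the alike libraries. That fit is among the 207, so its gained calls were fixed by the choice of genes.

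Replicate numbers did not pair libraries: of 30 pairs 1 correlated above 0.1, the highest at 0.106. As a block they brought a call of smooth muscle for age in Select (adjusted p = 0.0358; adjusted p = 0.542 with an estimated correlation). Matching list members by symbol alone was not run separately, since without product names it is the same as what was done. Depth may limit genes near 1 CPM, which was not tested separately. Thinning to 7314544 counts gave 40 calls between strains at 20 dph, 36 of them shared with the 51.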

Other observations

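Beyond the comparisons, genes outside the called lists moved with age; those named here were picked from called members of fixed lists. MHC class I genes went both ways: nlrc5, an activator of these genes, rose by 1.99 ± 0.26 in Commercial and 2.39 ± 0.27 in Select (log2 ± SE, n = 5), tapbpl by 2.56 and 1.70 and psmb8a, an immunoproteasome subunit, by 1.49 and 1.07, while the chaperone canx fell by 0.98 and 0.99. The class II invariant chain cd74b rose by 2.19 and 1.46. In the unfolded protein response list creld2 fell by 1.09 and 1.81 and edem1 by 1.44 and 1.06, while hsp70a rose by 2.25 and 1.90. The lists of MHC class I (adjusted p = 0.18 and 0.476) and unfolded protein response (0.0986 and 0.124) were not called by camera. With fry the adjusted p was 0.0192 and 0.109 for MHC class I and 0.00187 and 0.0029 for unfolded protein response.

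Transporters went both ways as well: npc1l1, which takes up cholesterol, fell by 1.95 and 1.71, and the peptide transporter slc15a1a by 1.30 and 0.94, while slc6a18, an amino acid transporter, rose by 3.44 and 2.64. Among pancreas genes ela2l, an elastase, fell by 3.62 and 2.77 and cpa5 by 3.88 and 3.59, while cuzd1.2 rose by 3.12 and 2.82. The exocrine pancreas list (adjusted p = 0.68 and 0.592) and the macrophage list (0.68 and 0.393) were not called by camera. With fry the adjusted p was 0.961 and 0.995 for the pancreas list and 0.138 and 0.022 for the macrophage list. In the growth hormone and IGF axis list called members went both ways, 3 higher and 1 lower of 18 in Commercial and 2 higher and 1 lower in Select, and the list was not called by camera (adjusted p = 0.993 and 0.842) or fry (0.961 and 0.506). Among them igf2r rose by 0.81 and 0.96.

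The values of gys2, a liver glycogen synthase, were chosen after they were seen, and no hypothesis was tested on them. It measured 15.2 ± 4.91 CPM in Commercial 20 dph (SD, n = 5) and 0.592 ± 0.711 in Select 65 dph. In Select 20 dph it measured 51.2 CPM in replicate 1 and 0.123 to 1.53 in the other 4, and in Commercial 65 dph 0.220 in replicate 2 and 16.2 to 35.4 in the other 4.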
